A study of Mus musculus with 8 samples.

How the data were processed

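RNA of thymic epithelial cells, labelled by cell population (medullary or cortical) and by Mcl1 genotype, was measured in 8 libraries of C57BL/6 mice. Per the labels, snap-frozen cell pellets gave RNA (miRNeasy Micro) that was amplified to cDNA with SMART-Seq v4, made into Nextera XT libraries and sequenced in paired ends on a NextSeq. The deposited values are raw counts per gene, which the authors made with featureCounts on mm10; the labels name no aligner, annotation, version, sort or gate. The files were checked to hold whole numbers with a different total in each library. A deposited table of the whole series has 8 per-sample columns whose names match no sample title; these columns were not mapped to samples and were not used.

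The groups held 4 wild-type cTEC, 2 wild-type mTEC, 1 knockout cTEC and 1 knockout mTEC library. Total counts were 19171953 and 18671044 in wild-type mTEC replicates 1 and 2; 13509642, 13300969, 18338441 and 18305050 in wild-type cTEC replicates 1 to 4; 11516780 in the knockout mTEC library; and 15314527 in the knockout cTEC library. A floor of 3 counts, used for every group at 0, corresponds to 0.194 CPM in the knockout cTEC library and 0.270 CPM in the knockout mTEC library. It was taken over the libraries of a group together. For 1 to 3 counts a ratio is given with its 95% counting interval. Intervals and floors cover counting error only, not variation between animals. Replicates were checked for duplicates: the chi-square per degree of freedom between libraries of 1 group was 23.7 for mTECs and 26.22 to 92.17 for cTECs.

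Counts were joined on NCBI gene IDs, and symbols and coordinates came from the RefSeq gene table of assembly GRCm38. Of 27179 IDs, 25275 had a symbol and 1904 had none; IDs without a symbol held 0.887% to 1.68% of the counts of a library. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20263. Library sizes were scaled by TMM factors of 0.954 to 1.04.

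Differences were tested with edgeR 4.0.16 (robust quasi-likelihood test, Benjamini-Hochberg adjusted p, threshold 0.05) in R 4.3.3. A group-means fit of all libraries (4 residual degrees of freedom, biological coefficient of variation 0.376) gave the comparison of wild-type mTECs with cTECs, the knockout contrast within each population and their difference, the interaction. An additive fit of population and genotype (5 residual degrees of freedom, coefficient 0.467) gave the knockout contrast over both populations. The SE of a log2 change is approximate: the absolute change divided by the square root of its quasi-likelihood F value. The 43 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, with adjustment over the lists of a comparison. Lists with fewer than 3 tested members were given values only. Medians of lists were taken with genes at 0 counts in an arm set at their bound where a caption says so. The lists, the comparisons, the naming rule and the alternatives were set before the data were examined. Exceptions were the lone-control setting and the tests that weigh an explanation. The overlap of contrasts, with its splits and omissions, was not in the plan of results either. Changes are described as a rise or fall only where they passed.

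Genes were named by rule. Mcl1 and every tested member of the pro-survival and pro-apoptotic BCL-2 lists could be named. For each comparison the rule added the 10 genes with the largest positive and the 10 with the largest negative log2 change among genes past the threshold. These had to have a curated symbol, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups; where too few passed, the 10 with the smallest p were taken and said not to have passed. Up to 4 members with the smallest p were added from each list described. Genes outside the rule are said to have been chosen after their values were seen.

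The tests were run on simulated data with the same group sizes and the dispersion of the group-means fit, with a known share of genes changed. Apart from these changes a gene had the same mean in all groups, and genes of very low level were not changed. Knockout effects that differ between the populations, which widen the spread of the real additive fit (coefficient 0.467 against 0.376), were absent. Recovery in the real data may therefore be lower. Genes changed 8-fold were recovered at 86.4% for wild-type mTECs against cTECs, at 84.8% in the additive knockout fit, at 69.7% for the knockout in cTECs and at 59.1% for the knockout in mTECs. At 4-fold the shares were 73.1%, 62.7%, 50.7% and 38.8%, and at 2-fold 17.9%, 16.4%, 7.46% and 1.49%. Each fold was set in 66 or 67 genes. Unchanged genes that were called numbered 10, 7, 10 and 4 in the same order. For the knockout in cTECs these 10 stood beside 5, 34 and 46 genes recovered at 2-fold, 4-fold and 8-fold. In each comparison false calls were a larger share of the calls than the threshold of 0.05 allows.

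Alternatives were other scalings (DESeq2 size factors, library totals), no and a stricter low-count filter, DESeq2 1.42.0, limma-voom with sample weights, a test against a 1.5-fold change, each population alone, a replicate block, leaving out each library in turn and wild-type cTEC replicate 1 as the lone cTEC control. The overlap of contrasts that share the wild-type cTEC libraries was compared with 6 splits of these libraries and with each wild-type library left out in turn; the latter was chosen after the overlap had been seen. Figures were drawn with matplotlib 3.10.9.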

Results

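Thymic epithelial cells form the stroma in which T cells mature: cortical cells (cTECs) drive the early stages and positive selection of thymocytes, and medullary cells (mTECs) display genes of other organs for tolerance. RNA from both populations of C57BL/6 mice was profiled in 8 libraries: 4 wild-type cTEC, 2 wild-type mTEC, 1 Mcl1 knockout cTEC and 1 Mcl1 knockout mTEC library. Levels are given as CPM, counts relative to library totals scaled by TMM factors. Gene p-values come from the edgeR quasi-likelihood test over 20263 genes, with Benjamini-Hochberg adjustment. Gene lists were tested with camera at a preset correlation of 0.01, and the values with an estimated correlation stand beside them. Each knockout group held 1 library, so its spread was assumed to be that of the other groups. The labels do not say whether replicates are separate animals, so p-values measure the spread between these samples only.

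Mcl1 encodes a pro-survival BCL-2 family protein that restrains mitochondrial apoptosis, and the change in its transcript differed between the knockout libraries. In the knockout cTEC library Mcl1 (gene ID 17210; chromosome 3, 95656944 to 95663179, assembly GRCm38, also called mm10) fell from 257.6 ± 32.5 CPM (mean and SD, n = 4) to 8.28 CPM, a log2 change of −4.96 ± 0.44 (SE; edgeR adjusted p = 0.000239). In the knockout mTEC library it stood at 78.5 CPM, below wild-type mTEC replicates 1 and 2 at 112.1 and 202.3 CPM. That log2 change of −1.0 ± 0.36 (SE) was not past the threshold (edgeR adjusted p = 0.576). The share of the wild-type level kept was 3.21% in cTECs (128 counts) and 49.9% in mTECs (871 counts). The difference between the populations passed by itself, at 3.96 ± 0.50 on the log2 scale (edgeR interaction test, adjusted p = 0.00244). The labels do not give the deleted part of Mcl1, and reads from a part left in place count toward the gene.

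**Figure D1:**
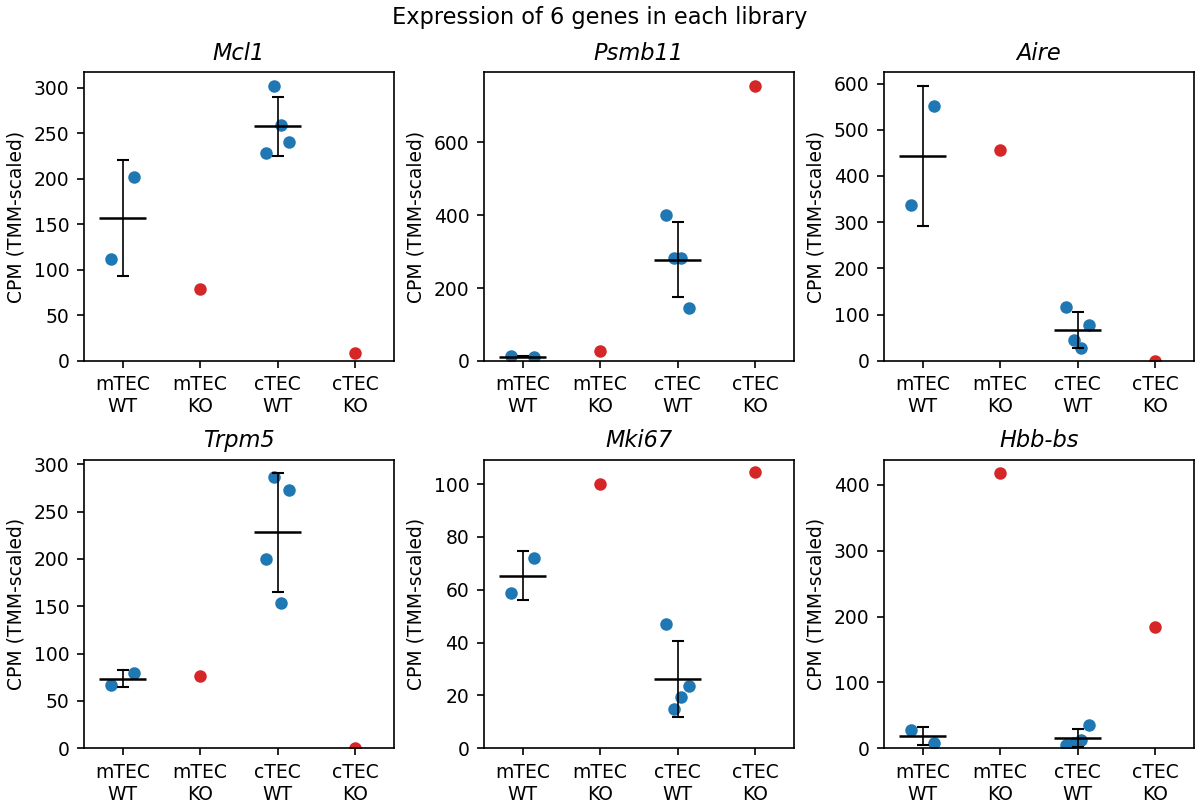
Levels of 6 genes in each library, in CPM scaled by TMM factors; lines and bars give the mean and SD of the wild-type groups. Mcl1 stands at 8.28 CPM in the knockout cTEC library and at 78.5 CPM in the knockout mTEC library; Aire, Mki67 and Hbb-bs were chosen after their values were seen.

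Wild-type mTECs and cTECs differed in tissue-restricted antigens and in cortical markers. Tissue-restricted antigens, which mTECs display to developing T cells, were higher in mTECs: Csn2, a milk casein, stood at 580.8 and 751 CPM in mTECs and at 97.56 to 126.4 CPM in cTECs. The cortical genes Psmb11, the catalytic subunit of the thymoproteasome, and Prss16, a thymus-specific serine protease, were lower in mTECs. Fezf2, a transcription factor that drives tissue-restricted antigens, was higher in mTECs, with log2 1.84 ± 0.18 (SE).

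Of 20263 genes tested between the wild-type populations, 5153 passed (2615 higher and 2538 lower in mTECs). Of 27 tissue-restricted antigens, 24 were higher, 0 lower and 3 not past (26 higher when adjusted over the list alone; camera adjusted p = 2.05e-16, and adjusted p = 0.279 with an estimated correlation). Csn2 was higher by 2.60 ± 0.17, Tnni1, slow skeletal troponin I, by 3.52 and Pcp4, a Purkinje cell protein, by 2.96. The pregnancy hormone Prl7d1 was at least 262-fold higher in mTECs, with the 4 cTEC libraries at 0 counts. Of 20 cTEC markers, 15 were lower and 5 not past (18 lower when adjusted over the list alone; camera adjusted p = 2.21e-19, and adjusted p = 0.228 with an estimated correlation). They included Psmb11 (gene ID 73902; chromosome 14, 54625310 to 54629556) at −4.61 ± 0.43, Prss16 at −4.22 ± 0.36 and the chemokine scavenger Ackr4 at −3.94 ± 0.20. Of 22 mTEC markers, 9 were higher, 4 lower and 9 not past (11 and 4 when adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.305 with an estimated correlation). Xcl1, a chemokine that attracts dendritic cells, was higher by 7.38 ± 0.90, and Trp63, an epithelial transcription factor, fell by 1.54 from cTECs to mTECs. The total count fell to 1149 without wild-type mTEC replicate 1, to 598 without replicate 2 and to 3174 without wild-type cTEC replicate 3.

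Some transcripts of tuft cells, chemosensory cells that also arise in the thymic medulla, were higher in the libraries labelled cTEC than in those labelled mTEC. Trpm5, their taste-signalling channel (gene ID 56843; chromosome 7, 143071529 to 143094642), stood at 67.18 and 79.8 CPM in mTECs and at 153.6 to 286.4 CPM in cTECs. Of 15 tuft-like genes, 0 were higher, 6 lower and 9 not past (9 lower when adjusted over the list alone; camera adjusted p = 0.0041, and adjusted p = 0.518 with an estimated correlation). Trpm5 was lower by log2 −1.63 ± 0.28, and its edgeR adjusted p became 0.0619 without wild-type mTEC replicate 1 and 0.0586 without replicate 2. The lipoxygenase Alox5 was also lower, at −1.50, with adjusted p = 0.0849 and 0.0658 without these libraries.

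Part of the growth factor receptor and interferon-stimulated genes were higher in cTECs, and part of the phagocyte and MHC class II genes in mTECs. Tgfbr2, a TGF-beta receptor, Egfr and Fgfr2 were lower in mTECs by −3.05, −2.04 and −1.90; in their list 7 of 11 genes were lower and 4 not past (7 when adjusted over the list alone; camera adjusted p = 1.86e-07, and adjusted p = 0.261 with an estimated correlation). Among 14 targets of FOXN1, the master regulator of thymic epithelium, 1 was higher, 10 lower and 3 not past (1 and 10 when adjusted over the list alone; camera adjusted p = 4.19e-11, and adjusted p = 0.305 with an estimated correlation). Interferon-stimulated genes counted 2 higher, 13 lower and 9 not past of 24 (2 and 14 when adjusted over the list alone; camera adjusted p = 0.000161, and adjusted p = 0.453 with an estimated correlation). The antiviral regulator Irf9 was lower by −1.11, with edgeR adjusted p = 0.0879 without wild-type mTEC replicate 2. The protease Ctss and the thiol reductase Ifi30, which act in MHC class II antigen processing, were higher in mTECs by 2.29 and 1.66. Of 14 genes of the MHC class II list, 8 were higher, 1 lower and 5 not past (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.518 with an estimated correlation). With cTEC replicate 1 as the lone cTEC library, where the spread came from the mTEC pair alone, 3 were higher and 2 lower. The MHC class I list counted 4 higher, 3 lower and 10 not past of 17 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.865), with a median of 0.16, a mean of −0.14 and a downward camera direction. Macrophage genes such as Lyz2, a lysozyme at 2.32, counted 7 higher, 1 lower and 4 not past of 12 (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0199, and adjusted p = 0.305 with an estimated correlation). Granulocyte genes such as S100a8, part of calprotectin at 3.94, counted 4 higher, 1 lower and 2 not past of 7 (6 and 1 when adjusted over the list alone; camera adjusted p = 5e-05, and adjusted p = 0.305 with an estimated correlation).

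Part of the mesenchymal and immediate early genes were higher in cTECs, and part of the cell cycle genes in mTECs. Dcn, a matrix proteoglycan, was lower in mTECs by −2.57, and its list counted 1 higher, 8 lower and 7 not past of 16 (3 and 10 when adjusted over the list alone; camera adjusted p = 3.5e-05, and adjusted p = 0.305 with an estimated correlation). Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, counted 11 lower and 7 not past of 18 (14 when adjusted over the list alone; camera adjusted p = 4.4e-06, and adjusted p = 0.464 with an estimated correlation). Their summed level was 29210, 20760 and 24500 CPM in wild-type cTEC replicates 2, 3 and 4 but 3612 CPM in replicate 1, close to the 3253 and 2053 CPM of the wild-type mTEC libraries. The median log2 change of the list was −2.63, and −0.39 with replicate 1 as the lone cTEC control. Fosb, an AP-1 subunit, was lower by −5.57, with edgeR adjusted p = 0.0777 without wild-type mTEC replicate 1 and 0.131 without replicate 2. Cell cycle genes counted 13 higher and 15 not past of 28 (15 when adjusted over the list alone; camera adjusted p = 0.000394, and adjusted p = 0.518 with an estimated correlation). Their summed level was 789.9 and 959.2 CPM in mTECs, 701.1 CPM in cTEC replicate 1 and 342.2 to 370 CPM in the other cTEC replicates.

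In the knockout cTEC library tuft-like genes and many medullary genes fell below the level that the wild-type cTEC libraries carried, and many cortical and proliferation genes rose. Gnat3, the taste G protein gustducin (gene ID 242851; chromosome 5, 17962570 to 18019668), and Trpm5 had 0 counts against 272.8 ± 46.9 and 228 ± 62.5 CPM (SD, n = 4) in wild-type cTECs. Aire, the regulator that opens tissue-restricted genes, stood at 28.97 to 116.3 CPM in wild-type cTECs and at 0 CPM in the knockout (chosen after its values were seen). Foxn1 rose from 129.1 ± 18.4 CPM to 530.8 CPM. Plk1, a mitotic kinase, rose by log2 3.08 ± 0.43 (SE).

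In knockout against wild-type cTECs 3079 of 20263 genes passed (895 rose and 2184 fell), and 512 of those that fell had 0 counts in the knockout. All 15 tuft-like genes fell, with 15 also when adjusted over the list alone (camera adjusted p = 4.01e-29, and adjusted p = 0.105 with an estimated correlation). Gnat3 was at least 1410-fold lower (edgeR adjusted p = 4.85e-05), Trpm5 at least 1180-fold and Rgs13, a regulator of G-protein signalling, at least 906-fold; Plcb2, a tuft-cell phospholipase, kept 1 count (1710-fold lower, counting interval 307 to 67600). Of 22 mTEC markers, 13 fell and 9 were not past (14 when adjusted over the list alone; camera adjusted p = 2.4e-14, and adjusted p = 0.0463 with an estimated correlation). Log2 changes were −8.35 ± 0.46 for Fezf2, −5.10 ± 0.27 for Tnfrsf11a, which encodes the receptor RANK, and −8.93 ± 0.60 for the T-cell attractant Ccl21a. Of 27 tissue-restricted antigens, 12 fell and 15 were not past (18 when adjusted over the list alone; camera adjusted p = 3.54e-12, and adjusted p = 0.126 with an estimated correlation), with Csn2 at least 566-fold lower. Of 10 microfold-like genes, 9 fell and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 7.08e-13, and adjusted p = 0.105 with an estimated correlation). Spib, a transcription factor of microfold cells, fell by 7.67. Among keratinized epithelium genes 8 fell and 7 were not past (10 when adjusted over the list alone; camera adjusted p = 1.42e-08, and adjusted p = 0.2 with an estimated correlation).

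**Figure D2:**
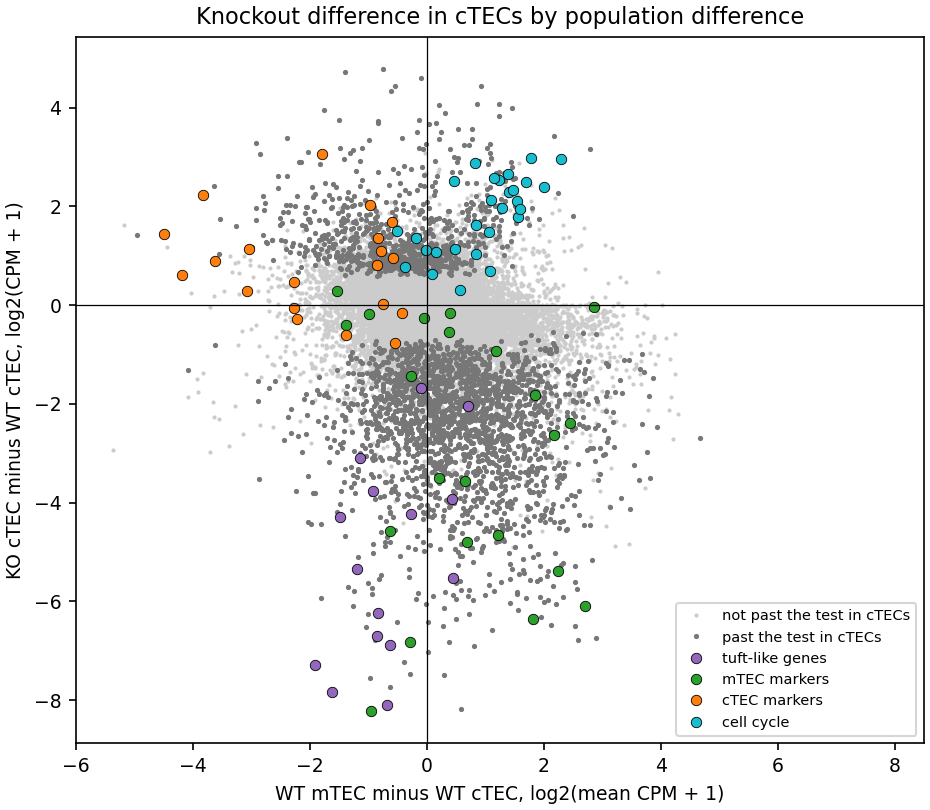
Each dot is a gene; x, difference between wild-type mTECs and wild-type cTECs; y, difference between knockout and wild-type cTECs, each as log2 of the mean CPM plus 1, with 4 lists coloured. All 15 tuft-like genes lie below 0 on the y axis, while 18 of 28 cell cycle genes were called higher in the knockout.

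Part of the cTEC markers stood higher in the knockout cTEC library. Their summed level was 19030 CPM in the knockout, 15830 CPM in wild-type replicate 1 and 9884 to 12610 CPM in replicates 2 to 4. The median log2 change of the list was 0.85, and 0.61 with replicate 1 as the lone cTEC control. Of 20 cTEC markers, 9 rose and 11 were not past (10 and 1 rose and fell when adjusted over the list alone; camera adjusted p = 6.5e-07, and adjusted p = 0.126 with an estimated correlation). Ackr4 rose by 2.25 ± 0.18, Foxn1 by 2.04 ± 0.20 and Pax1, a transcription factor of pharyngeal endoderm, by 1.13 ± 0.20. Cell cycle genes counted 18 higher and 10 not past of 28 (21 when adjusted over the list alone; camera adjusted p = 4.16e-16, and adjusted p = 0.207 with an estimated correlation). Birc5, a mitotic regulator, rose by 2.65 and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by 3.11. The summed cell cycle level was 1597 CPM in the knockout, 701.1 CPM in wild-type replicate 1 and 342.2 to 370 CPM in the other wild-type replicates. Ribosomal protein genes counted 6 higher and 22 not past of 28 (11 when adjusted over the list alone; camera adjusted p = 9.52e-08, and adjusted p = 0.434 with an estimated correlation), with Rplp0, a stalk protein, up by 1.07. The genes with the largest rises were not cortical markers: Lmo3, a transcriptional cofactor, rose from 1.65 to 56.18 CPM, Cthrc1, a secreted matrix protein, from 2.84 to 105.0 CPM and the oestrogen receptor Gper1 from 2.61 to 77.26 CPM.

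BCL-2 family members besides Mcl1 fell in the knockout cTEC library on both sides of the apoptotic balance. The NF-kB-inducible survival genes Bcl2a1b and Bcl2a1a had 0 counts (at least 220-fold and 55.8-fold lower; edgeR adjusted p = 5.22e-05 and 0.000192), and Bcl2a1d kept 2 counts (164-fold lower, counting interval 45.3 to 1350). Pmaip1, which encodes NOXA, a BH3-only protein that binds MCL1, fell by 6.77 ± 0.54 (edgeR adjusted p = 0.000162), and Bik, a killer of the same class, had a log2 change of −5.20 ± 0.51. Bok, an effector relative, rose by 1.05, with edgeR adjusted p = 0.0545 and 0.053 without wild-type mTEC replicates 1 and 2 and 0.057 without wild-type cTEC replicate 2. Of 7 pro-survival genes, Mcl1 included, 4 fell and 3 were not past (4 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.28e-06, and adjusted p = 0.105 with an estimated correlation). Of 11 pro-apoptotic genes, 1 rose, 2 fell and 8 were not past (2 and 4 when adjusted over the list alone; camera adjusted p = 0.136). Not past were Bcl2 at 0.81 (adjusted p = 0.121), Bcl2l1, which encodes BCL-XL, at −0.17 (0.74) and Bcl2l11, which encodes BIM, at −1.36 (0.0814). Between the wild-type populations, 3 of the 7 pro-survival genes were higher in mTECs, Bcl2a1a among them, 1 lower and 3 not past. That list gave camera adjusted p = 0.0386, and adjusted p = 0.305 with an estimated correlation. Of the 11 pro-apoptotic genes 1, Bik, was higher in wild-type mTECs and 10 were not past (camera adjusted p = 0.449). Bcl2a1a and Bik lost these calls without either wild-type mTEC library.

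Part of the chemokine, NF-kB target and interferon-stimulated genes were lower in the knockout cTEC library, while most genes of the MHC lists were not past the threshold. B2m, the light chain of MHC class I, and its regulator Nlrc5 had log2 changes of −2.56 and −3.54; in the MHC class I list 5 of 17 genes fell, 1 rose and 11 were not past (5 and 1 when adjusted over the list alone; camera adjusted p = 0.261). In the MHC class II list 1 gene rose, 1 fell and 12 were not past of 14 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.776), with a median change of 0.02, a mean of −0.49 and an upward camera direction. The gene that fell was Ctss, at −4.99. Of 16 chemokine genes, 7 fell and 9 were not past (8 when adjusted over the list alone; camera adjusted p = 2.82e-06, and adjusted p = 0.105 with an estimated correlation). The interferon-induced chemokine Cxcl9 fell by 5.76. NF-kB targets counted 9 lower, 1 higher and 5 not past of 15 (12 and 1 when adjusted over the list alone; camera adjusted p = 4.88e-06, and adjusted p = 0.105 with an estimated correlation). Among them Traf1, a TNF receptor adaptor, fell by 3.61. Interferon-stimulated genes counted 11 lower and 13 not past of 24 (14 when adjusted over the list alone; camera adjusted p = 2.8e-06, and adjusted p = 0.386 with an estimated correlation), with Irf7, a master regulator of type I interferon, down by log2 −1.70. The p53 target Cdkn1a, a brake on cell division, fell by 4.23, while its list counted 3 higher, 2 lower and 20 not past of 25 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.937). Genes of fatty acid oxidation counted 5 higher, 1 lower and 9 not past of 15 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.00136, and adjusted p = 0.152 with an estimated correlation). Cpt1a, the step that admits fatty acids to mitochondria, rose by 1.45.

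Transcripts of other cell types moved apart in the knockout cTEC library. Some granulocyte genes fell, with S100a8 at least 52.9-fold lower, and their list counted 4 lower and 3 not past of 7 (4 when adjusted over the list alone, camera adjusted p = 0.00134, and adjusted p = 0.207 with an estimated correlation). Macrophage genes such as Lyz2, which fell by 4.21, counted 6 lower and 6 not past of 12 (1 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.00331, and adjusted p = 0.126 with an estimated correlation). Parathyroid genes counted 2 lower and 2 not past of 4 (2 when adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.434 with an estimated correlation), with a summed level of 0.323 CPM in the knockout and of 249.5, 105.6, 28.1 and 37.15 CPM in wild-type cTEC replicates 1 to 4. B-cell genes counted 2 lower and 8 not past of 10 (2 when adjusted over the list alone; camera adjusted p = 0.0087, and adjusted p = 0.152 with an estimated correlation). Erythroid genes counted 5 higher and 4 not past of 9 (5 when adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.152 with an estimated correlation). The haem synthesis gene Alas2 rose by 2.26, and the alpha-globin Hba-a1 by 3.99. Mesenchymal genes counted 5 higher, 2 lower and 9 not past of 16 (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.434 with an estimated correlation). Col1a1, the chain of collagen I, rose by 3.04, while Fn1, fibronectin, fell by 1.46. Mitochondrial-encoded transcripts, which also vary with RNA quality, counted 3 lower and 10 not past of 13 (7 when adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.646 with an estimated correlation).

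In mTECs no gene passed by edgeR between knockout and wild type. The edgeR count was 0 of 20263 genes, with 1595 at unadjusted p under 0.05, 147 by DESeq2 and 28 by limma-voom. A fit of the mTEC libraries alone called 1483 genes, and a fit with cTEC replicate 1 as the lone wild-type cTEC library 1376; in each the spread came from the wild-type mTEC pair alone. Without wild-type cTEC replicate 1, which enters through the shared dispersion, the edgeR count was 11. The genes with the smallest p were Bpifa1, a secreted airway protein at 435.6 CPM in wild type and 2278 CPM in the knockout, Dcn at 113.3 and 573.9 CPM, and Bgn, a matrix proteoglycan at 4.93 and 40.74 CPM (edgeR adjusted p = 0.0861 for each). Medullary genes stayed near their wild-type levels: Aire stood at 455.4 CPM in the knockout against 336.6 and 550.4 CPM, Fezf2 at 386.3 CPM against 349.4 and 419.4 CPM, and Trpm5 at 76.07 CPM against 67.18 and 79.8 CPM.

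Over the lists no member passed among all genes, so the counts here are those adjusted over the list alone. Mesenchymal genes gave 12 higher of 16 (camera adjusted p = 1.99e-24, and adjusted p = 0.221 with an estimated correlation); Col1a1 stood at 110.9 CPM against 8.32 and 13.76 CPM. Erythroid genes gave 5 of 9 (camera adjusted p = 1.44e-06, and adjusted p = 0.221 with an estimated correlation), with the beta-globin Hbb-bs at 417.8 CPM against 28.34 and 8.25 CPM. Cell cycle genes gave 1 of 28 (camera adjusted p = 1.53e-08, and adjusted p = 0.556 with an estimated correlation), and Mki67, a proliferation antigen, stood at 100.2 CPM against 58.7 and 72.03 CPM. cTEC markers gave 2 of 20 (camera adjusted p = 9.48e-06, and adjusted p = 0.556 with an estimated correlation), with Psmb11 at 26.41 CPM against 12.75 and 10.09 CPM. Ribosomal protein genes gave 0 of 28 (camera adjusted p = 5.94e-07, and adjusted p = 0.592 with an estimated correlation). Endothelial genes gave 0 of 12, with a median log2 change of 1.22 (camera adjusted p = 0.000126, and adjusted p = 0.556 with an estimated correlation). Mitochondrial-encoded transcripts gave 0 of 13, with a median of −0.79 (camera adjusted p = 0.000114, and adjusted p = 0.592 with an estimated correlation). Tuft-like genes, mTEC markers and tissue-restricted antigens gave 0 each, with camera adjusted p = 0.18, 0.172 and 0.444 and median log2 changes of −0.24, 0.07 and −0.07. Both BCL-2 family lists gave camera adjusted p above the threshold, at 0.637 for pro-survival and 0.215 for pro-apoptotic genes. The latter had a median change of −0.13, a mean of 0.07 and an upward camera direction; Pmaip1 was at 1.01 (edgeR adjusted p = 0.548), Bcl2a1b at 0.46 (0.667) and Bcl2l1 at 0.04 (0.994).

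The knockout effect differed between the populations for tuft-like genes and for part of the medullary genes, with the more positive change in mTECs. Between the contrasts 1201 of 20263 genes differed: 1092 with the more positive change in mTECs and 109 with the more positive change in cTECs. The count was 649 and 660 without wild-type mTEC replicates 1 and 2 and 1822 without wild-type cTEC replicate 1. All but 1 of 15 tuft-like genes differed, 14 with the more positive change in mTECs (15 when adjusted over the list alone; camera adjusted p = 6.61e-39, and adjusted p = 0.0637 with an estimated correlation). Trpm5 and Gnat3 differed with edgeR adjusted p = 0.000269 and 0.000123. Of 22 mTEC markers, 12 were more positive in mTECs and 10 not past (15 when adjusted over the list alone; camera adjusted p = 8.64e-22, and adjusted p = 0.0173 with an estimated correlation), with Fezf2 at 8.35 ± 0.50 and Tnfrsf11a at 5.0 ± 0.31. Tissue-restricted antigens counted 8 and 19 not past of 27 (14 when adjusted over the list alone; camera adjusted p = 7.24e-15, and adjusted p = 0.102 with an estimated correlation). Pro-survival genes counted 4 and 3 not past of 7 (4 when adjusted over the list alone; camera adjusted p = 1.82e-09, and adjusted p = 0.0632 with an estimated correlation). Bcl2a1b stood at 178.2 CPM in knockout mTECs, and differed with adjusted p = 0.000123. Of 20 cTEC markers, 1 was more positive in cTECs and 19 not past (camera adjusted p = 0.0289, and adjusted p = 0.512 with an estimated correlation): Foxn1, at −1.78 ± 0.33, whose edgeR adjusted p became 0.0582 and 0.0628 without wild-type mTEC replicates 1 and 2. None of 28 cell cycle genes and none of 9 erythroid genes differed between the populations (camera adjusted p = 3.36e-05 and 0.962; cell cycle adjusted p = 0.545 with an estimated correlation). The erythroid list had a median of 0.93, a mean of 0.10 and a downward camera direction.

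**Figure D3:**
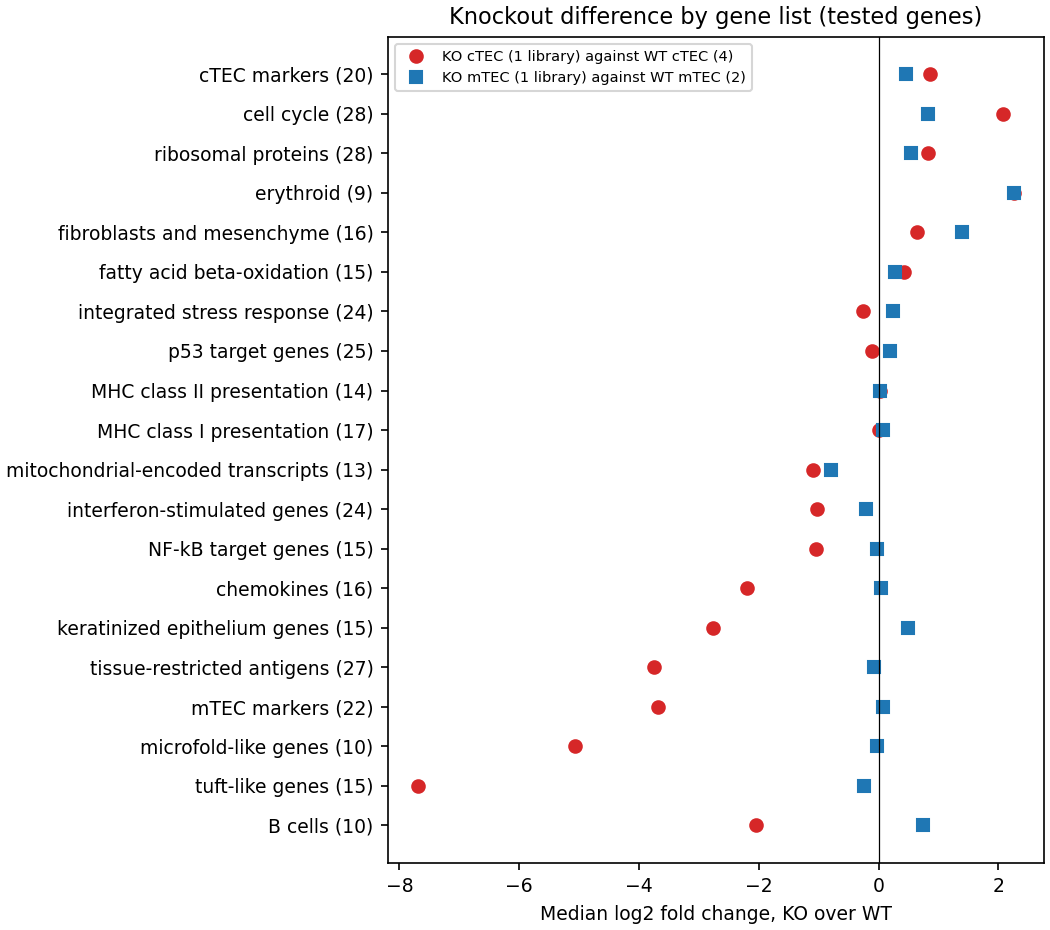
Median log2 change from wild type to knockout of 20 gene lists in cTECs and mTECs, with genes at 0 counts set at their bound and the number of tested genes in parentheses. Tuft-like genes have a median of −7.69 in cTECs and −0.24 in mTECs.

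Taken over both populations in an additive fit, few genes passed by edgeR. Il33, an alarmin cytokine, stood at 8.12 and 43.89 CPM in wild-type and knockout mTECs and at 67.87 and 669 CPM in cTECs. Serpinf1, a secreted serpin, stood at 8.04 and 53.36 CPM in mTECs and at 64.19 and 544.7 CPM in cTECs. Tnfrsf19, a TNF receptor of progenitor epithelia, stood at 6.01 and 27.67 CPM in mTECs and at 22.8 and 365.7 CPM in cTECs.

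The additive fit called 37 genes of 20263 by edgeR (33 rose and 4 fell) and 1555 by DESeq2. The lowest edgeR adjusted p was 0.00686, for Serpinf1 at 2.93 ± 0.22 and Abat, a GABA transaminase, at 2.48 ± 0.20. Il33 rose by 2.94 ± 0.29, Tnfrsf19 by 3.33 ± 0.34 and Col1a1 by 3.17 ± 0.35. Of 28 cell cycle genes, 1 rose and 27 were not past (25 when adjusted over the list alone; camera adjusted p = 5.34e-23, and adjusted p = 0.324 with an estimated correlation); the gene was Mcm5, a replication helicase subunit. Of 20 cTEC markers, 2 rose and 18 were not past (10 when adjusted over the list alone; camera adjusted p = 1.6e-09, and adjusted p = 0.288 with an estimated correlation), namely Ackr4 at 1.88 ± 0.19 and Pax1 at 1.08 ± 0.14. Of 16 mesenchymal genes, 1 rose and 15 were not past (8 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.32e-09, and adjusted p = 0.288 with an estimated correlation). Of 9 erythroid genes, 1 rose, Alas2, and 8 were not past (5 when adjusted over the list alone; camera adjusted p = 1.74e-07, and adjusted p = 0.171 with an estimated correlation). Mcl1 was at −2.53 ± 0.96 with edgeR adjusted p = 0.247, not past. Serpinf1 and Abat kept their calls with each wild-type library left out, while Pax1 and Mcm5 lost theirs without any 1 of the 6 wild-type libraries (edgeR adjusted p from 0.0505 to 0.146 and from 0.0578 to 0.113). Without wild-type cTEC replicates 2 and 3 adjusted p was 0.06 and 0.0517 for Il33, 0.061 and 0.0517 for Ackr4, 0.061 and 0.0517 for Alas2, and 0.0913 and 0.0659 for Tnfrsf19. Without wild-type mTEC replicate 2 it was 0.0554 for Tnfrsf19, 0.0636 for Col1a1 and 0.0691 for Alas2; Col1a1 was at 0.0856 and 0.0555 without wild-type cTEC replicates 2 and 4, and Tnfrsf19 at 0.0673 without replicate 4. The count was 0 without the knockout cTEC library, where Serpinf1 was at 0.115 and Mcm5 at 0.362, and 3133 without the knockout mTEC library, where the contrast becomes that of cTECs alone. It was 23 and 10 without wild-type mTEC replicates 1 and 2, and 16, 6, 4 and 15 without wild-type cTEC replicates 1 to 4.

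Changes that passed in cTECs were set beside the sign of the change in mTECs, where no gene passed by edgeR. Of 895 genes that rose in knockout cTECs, 724 (80.9%) had a positive change in mTECs, and of 2184 that fell, 1419 (65%) had a negative change. Across all 20263 genes, which are not independent replicates, the log2 changes in the populations had a Pearson correlation of 0.162 and a Spearman correlation of 0.262, with the same sign for 61.4%. No library enters both contrasts.

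The genes that fell in knockout cTECs overlapped with those that mTECs hold at a higher level. Of the genes past the threshold, 730 were higher in wild-type mTECs than in wild-type cTECs and lower in knockout than in wild-type cTECs, where 281.9 would be expected from independent lists. In the other direction, 362 were lower in mTECs and higher in the knockout, with 112.1 expected. Both contrasts use the wild-type cTEC libraries; over 6 splits that gave each contrast its own pair of wild-type cTEC libraries the first overlap averaged 613.2 genes (428 to 837), with 174.5 expected. The first overlap was 229 genes without wild-type mTEC replicate 1 (41.17 expected) and 158 without replicate 2 (22.26 expected). With a wild-type cTEC library left out it ran from 524 without replicate 3 (147.5 expected) to 1015 without replicate 1 (527.6 expected). The second was 133 and 107 without these mTEC libraries (18.52 and 9.95 expected), and 208 without wild-type cTEC replicate 3 (48.19 expected). Of the 2184 genes that fell, 669 had the lower mean in wild-type mTECs, the tuft gene Trpm5 among them.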

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

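Every test that weighs an explanation here was chosen after the results were seen; the interaction tests were planned, and the test for outlying libraries had a preset criterion.

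The knockout effect differed between mTECs and cTECs for 1201 genes by the edgeR interaction test. Among named genes whose change was more positive in mTECs, adjusted p was 0.000269 for Trpm5, 0.000123 for Gnat3, 0.0265 for the neuroendocrine granin Chga, 0.000593 for Rgs13, 0.000123 for Csn2, 0.00428 for the chitinase-like Chil4, 0.000123 for Hepacam2, 0.0306 for the trypsin inhibitor Spink1, 0.00279 for Krt20 and 0.000847 for Cdhr5. All 10 had 0 counts in the knockout cTEC library. Without wild-type mTEC replicates 1 and 2 Chga was at 0.0718 and 0.0651 and Spink1 at 0.0727 and 0.0785; Chga was at 0.0534 without wild-type cTEC replicate 2. Within the BCL-2 family the values were 0.00244 for Mcl1, 0.000644 for Bcl2a1a, 0.000123 for Bcl2a1b, 0.000269 for Bcl2a1d, 0.00036 for Pmaip1 and 0.00161 for Bik. The list of mTEC markers passed with an estimated correlation, at 0.0173.

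Among genes whose change was more positive in cTECs, the interaction adjusted p was 0.0151 for Rerg, 0.0209 for the glucose transporter Slc2a3, 0.0218 for Lpar5, 0.0217 for Baiap3, 0.0498 for Cacng4, 0.0124 for the glypican Gpc6, 0.0398 for the collagen Col13a1, 0.0162 for Lmo3, 0.0101 for the natriuretic peptide receptor Npr1 and 0.0497 for Zfp9. Leaving out wild-type mTEC replicate 2 ended the call of Slc2a3 (0.056), Lpar5 (0.0602), Baiap3 (0.0714), Cacng4 (0.157), Col13a1 (0.109), Lmo3 (0.0604) and Zfp9 (0.11). Leaving out replicate 1 ended that of Lpar5 (0.0659), Baiap3 (0.0523), Cacng4 (0.0611), Col13a1 (0.112) and Zfp9 (0.142). Wild-type cTEC libraries mattered for 3 of these genes: without replicate 2, Cacng4 was at 0.0656, Col13a1 at 0.073 and Zfp9 at 0.0705; without replicate 3 at 0.0854, 0.0676 and 0.0911; and Zfp9 at 0.0594 without replicate 4.

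Some wild-type cTEC libraries lay far from the other replicates, by a Dixon gap test on 119 series of 4 values. The test marked 12 of them, where chance marks about 5%. Replicate 1 was low in summed heat shock genes (3128 CPM) and in epithelial progenitor and mesenchymal-like genes (2408 CPM), and high in cell cycle genes (701.1 CPM). It was also apart in Lypd8 (221.6 CPM), Ptgs2 (234.0 CPM) and Gpc6 (9.07 CPM). In summed immediate early, heat shock and cell cycle genes, however, replicates 2 to 4 stood apart from every other library. Immediate early sums were 20760 to 29210 CPM there, and 4406 and 6794 CPM in the knockout mTEC and cTEC libraries. Heat shock sums were 11710 to 12390 CPM there, and 6652 and 9008 CPM in those knockout libraries. From wild-type to knockout cTECs the median log2 change of immediate early genes was −1.48, and 0.48 with replicate 1 as the lone control. Replicate 2 was apart in Bcl2l11 (20.83 CPM), Pmaip1 (147.4 CPM) and Bak1 (3.03 CPM), and replicate 3 in Hepacam2 (120.6 CPM). Replicate 4 was apart in the summed erythroid genes (140.1 CPM) and in Chrna4 (2.63 CPM).

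The first pattern is the fall of all 15 tuft-like genes and of 25 mTEC markers and tissue-restricted antigens in the knockout cTEC library. For the tuft-like genes the values argue against RNA of the whole mTEC population in the wild-type cTEC libraries as the whole cause, as far as their higher level in wild-type cTECs holds. The median share that their level would need was at least 1.3 in each of the 4 libraries, more than mTEC RNA alone could give. In a library 10 to 14 of the 15 genes needed a share above 1. Such a share restates the higher level in cTECs, where 6 of 15 genes passed and camera gave adjusted p = 0.518 with an estimated correlation. The spread between the 2 wild-type mTEC libraries was not weighed. For the called mTEC markers and antigens the median needed share was 0.218 to 0.376. It varied over genes, with a 90th to 10th percentile ratio of at least 5.55, where 1 share would serve all. This spread cannot decide the question. The genes were picked as lower in the same data, and the spread that variation between libraries gives was not worked out. For the tuft-like genes loss of single transcripts at random, each gene for itself, is also argued against, since 0 of 10000 expression-matched lists had as many genes lower; for the markers and antigens it was not tested. Lower depth is argued against for both, since the knockout total was 1.15 times the lowest wild-type total, although the knockout library held the fewest genes with a count (17800, against 18704 to 20405 in wild-type cTECs). Still open and untested are loss of such cells in the knockout, their chance absence from a small input, and a tuft-rich subset of mTECs among the cells labelled cTEC in wild type but not in the knockout; the labels name no gate that separates these.

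The second pattern is the higher level of mesenchymal genes in the knockout mTEC library. For the 12 members that were higher when adjusted over the list alone, RNA of cTECs is argued against as the whole cause. The lowest cTEC share needed was 0.251, for Pdgfc, and the median was 2.38, while Psmb11 and Prss16 give shares of 0.0562 and 0.0485. These members were picked as higher in the same library, which raises the median, and the other listed genes were not weighed. RNA of mesenchymal cells and an effect of the genotype on epithelial cells cannot be told apart with 1 library: the 14 of 16 listed genes above both wild-type mTEC libraries, led by Dcn at 573.9 CPM, restate the pattern, and 11 of the 16 reach 10 CPM in wild-type mTECs and 11 in wild-type cTECs. Other cell types' lists were higher in the knockout mTEC library as well: erythroid genes at 1702 CPM in sum against 111.8 and 51.7 CPM (7 of 9 above both wild-type libraries; camera adjusted p = 1.44e-06, and adjusted p = 0.221 with an estimated correlation), endothelial genes at 278 against 187.3 and 99.4 CPM (0.000126, and adjusted p = 0.556 with an estimated correlation) and parathyroid genes at 500.7 against 113.1 and 121.9 CPM (0.172, not past). In the knockout cTEC library 7 of the 16 mesenchymal genes lay above the wild-type range. Of all 20263 genes, 80.42% lay outside the wild-type range on either side in the knockout mTEC library. In the knockout cTEC library the share was 57.81%. These shares count genes above and below the range together, unlike the counts of mesenchymal genes above it. The share of all genes above the range was not worked out.

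The third pattern is the Mcl1 transcript left in the knockout mTEC library. If both libraries carry the same deleted allele, reads from a remaining part of the gene would leave an equal share in each; the shares were 3.21% in cTECs and 49.9% in mTECs (interaction adjusted p = 0.00244), which argues against such reads as the whole cause. Cells with an undeleted gene in the knockout mTEC library may account for the rest, which was not tested. Such cells would also dilute a knockout effect in that library.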

How the results depend on the processing

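The setting with wild-type cTEC replicate 1 as the lone cTEC control was chosen after its immediate early level had been seen. In the group-means fit its spread comes from the 2 wild-type mTEC libraries alone. In the additive fit knockout effects that differ between the populations enter its spread as well. The other settings were planned.

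Between wild-type mTECs and cTECs 5153 genes passed, 9896 with limma-voom and 2240 against a 1.5-fold change; leaving out 1 library gave 598 to 7146. With a replicate block over the 6 wild-type libraries 2320 passed and with a replicate block on shared numbers 2138. Deviations from the group mean had correlations of −0.112 and −0.00435 at equal numbers. With 2 wild-type mTEC libraries these deviations mirror each other, so the correlations cannot tell whether the numbers mark pairs. The additive knockout count of 37 became 58 without a low-count filter, 1555 with DESeq2, 22 with limma-voom, 15 against a 1.5-fold change, 2340 as the average of the contrasts within each population and 0 with cTEC replicate 1 as the lone cTEC control; leaving out 1 library gave 0 to 3133. The cTEC knockout count of 3079 became 6426 with that lone control and ranged from 2190 to 4113 over single omissions. In mTECs the count of 0 became 147 with DESeq2, 28 with limma-voom, 1483 with mTEC libraries alone and 1376 with the lone control, and single omissions gave 0 to 11. The interaction count of 1201 became 2066 with DESeq2, 548 with limma-voom and 4457 with the lone control, and single omissions gave 649 to 1822. The correlation of knockout effects between populations was 0.162, 0.203 for genes of at least 10 CPM, and 0.142 to 0.172 over single omissions. The averaged contrast weighs each population equally and comes from the group-means fit. Its biological coefficient of variation was 0.376, against 0.467 in the additive fit. The additive fit has no interaction term, so knockout effects that differ between the populations enter its spread. Single-population fits estimate the spread from fewer libraries. Otherwise the cause was not tested.

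Lists past the threshold numbered 25 for wild-type populations, 19 for the additive knockout, 23 in cTECs, 16 in mTECs and 22 for the interaction. With an estimated correlation they were 0, 0, 1, 0 and 1. A fry test, which asks whether the genes of a list move together, called 27, 1, 19, 0 and 14 in the same order.

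No named gene that had passed changed its direction. Reversed signs were all in BCL-2 family genes that had not passed. Of the genes that had not passed, only BCL-2 family members and, in mTECs, the 10 with the smallest p were followed over the settings. Whether other list members kept their sign was therefore not examined. The values are fitted log2 changes, which for genes at 0 counts are no bounds. Between wild-type populations these were Bad (−0.030 with the lone control), Bak1 (−0.0092 with library totals, −0.15 with the lone control, −0.10 to 0.091 over single omissions) and Pmaip1 (−0.12 to 0.64 over single omissions). In the additive fit single omissions gave −0.17 to 0.041 for Bcl2l1, −10.5 to 0.40 for Bcl2a1a, −12.48 to 0.46 for Bcl2a1b, −7.27 to 0.39 for Bcl2a1d and −6.77 to 1.01 for Pmaip1. Omitting the knockout mTEC library leaves the cTEC contrast at the lower ends, and omitting the knockout cTEC library the mTEC contrast at the upper ends. In cTECs Bid was at −0.12 with the lone control, and Bax at −0.052 with the stricter filter and −0.039 with cTECs alone. Over single omissions Bax ranged from −0.18 to 0.23 and Bcl2l1 from −0.27 to 0.010. In mTECs single omissions gave −0.022 to 0.23 for Bcl2 and −0.0059 to 0.083 for Bcl2l1. Apart from the additive fit, the cause was not tested.

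Of the named genes that were followed over all settings, 2719 values kept side and sign between wild-type populations and 375 lost the call, 94 of them without wild-type mTEC replicate 2. In cTECs 2112 kept both and 100 lost the call. Depth limits genes at 0 counts in a knockout library to a lower bound.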

Other observations

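Xist and Ddx3y were chosen after their values were seen and are given as values alone; the test of the mitochondrial-encoded list was planned.

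Sex-linked transcripts varied between libraries of a group. Xist, which is transcribed from the inactive X chromosome of females, stood at 395 CPM in wild-type mTEC replicate 2 and at 4.05 CPM in replicate 1. It stood at 200.8 CPM in wild-type cTEC replicate 1 and at 5.39, 10.65 and 10.85 CPM in replicates 2, 3 and 4. The knockout mTEC and cTEC libraries held 64.62 and 71.7 CPM. Ddx3y, from the Y chromosome, stood at 147.2 and 44.24 CPM in the wild-type mTEC libraries, 71.54, 105.8, 125.4 and 102.2 CPM in the wild-type cTEC libraries, and 82.2 and 72.86 CPM in the knockout mTEC and cTEC libraries. Both transcripts were present in every library.

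Mitochondrial transcripts took a share of 3.34% and 3.07% of counts in the wild-type mTEC libraries and 1.08% to 1.87% in the wild-type cTEC libraries. In the knockout mTEC and cTEC libraries the share was 2.14% and 0.698%. Of 13 mitochondrial-encoded transcripts, 8 were higher in wild-type mTECs than in cTECs and 5 not past (camera adjusted p = 0.000267, and adjusted p = 0.464 with an estimated correlation). In the additive knockout fit 0 passed among all genes, and 9 were lower when adjusted over the list alone. The camera direction there was downward (camera adjusted p = 2.94e-05, and adjusted p = 0.589 with an estimated correlation).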
